A study of Mus musculus with 54 samples.

How the data were processed

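RNA-seq was measured in 54 libraries of mouse 4T1 cells, a mammary carcinoma line that metastasises from the mammary gland in mice. The libraries came from 23 clones, each grown from a single sorted cell, and from 4 specimens taken from mice, namely 2 orthotopic tumors and 2 lung metastases. Each clone and each specimen had 2 libraries, lettered A and B. The labels call clones E and T intravasating, meaning that their cells were found to enter the blood stream, and call the other 21 clones non-intravasating. Nothing in the labels says whether the 2 libraries of a clone came from separate cultures, so a p-value that rests on libraries measures only the spread between those 2 libraries, which may be technical. The labels do not say whether tumor cells were sorted away from mouse tissue before RNA was taken from the specimens.

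Per the labels' protocols, total RNA was purified with a column kit and treated with DNase, 100 ng was amplified to cDNA with a NuGEN Ovation kit, the cDNA was sheared by sonication, and libraries were sequenced on a HiSeq instrument with reads of 76 bases. Per the submitters' processing notes, Bowtie2, HTSeq and DESeq were used with the mouse genome build mm10. Their versions and settings are not given in the sources used here, and neither is the strand setting of the counting. Reads from overlapping genes, from antisense partners and from near-identical copies such as the H2 genes of MHC class I can therefore not be told apart.

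The authors deposited log2 values in 1 table of 23481 genes by 54 libraries. Read from the values themselves, they follow a variance-stabilising curve, on which a gene without reads sits at 5.03 and high values approach the log2 of the normalized count. A difference between low genes is therefore smaller on this scale than the log2 ratio of their counts. Inverting the curve gave normalized counts, and dividing these by the value of 1 read in each library gave whole reads, within 0.01 of a whole number, for 100% of the values. These recovered reads gave the depth of each library, and the normalized counts printed in the text are means over the 2 libraries of a clone or specimen. Differences and their standard errors are on the deposited log2 scale. The design fixed in advance had assumed values that need log2(value + 1). The deposited values were already on a log2 scale, so the tests ran on them as deposited, and log2(recovered normalized count + 1) was an added alternative. A test for counts was not run, because the deposited unit is log2.

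There were 0 columns without a sample. In 27 rows the gene symbol had been turned into a date by spreadsheet software, and these rows are not named in the text. In 1316 rows no library had a read. Genes with a normalized count of at least 10 in at least 2 of the libraries of a comparison were tested, which left 13637 genes for the clones and 13702 for the specimens. The 2 libraries of a clone or specimen were never identical. Their correlation across genes lay between 0.950 and 0.997, and the chi-square of their reads per gene lay between 5.01 and 139.4, above sampling noise in all 27 pairs.

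Tests were made in R 4.3.3 with limma 3.58.1, two-sided, with a trend of the variance on the mean, Benjamini-Hochberg adjustment and a threshold of 0.05. The intravasating clones were compared with the other clones on 1 value per clone, the mean of its 2 libraries. The same clones were ranked against the others without a model. The rule that the labels describe, higher in both clones than in at least 11 of the 21 others, was applied with limma contrasts over the 46 clone libraries, adjusted within each contrast, and also to all 253 pairs of clones. Clones E and T were compared with each other, and all 23 clones together by a moderated F-test, in the same fit. Lung metastases were compared with orthotopic tumors on 1 value per specimen. The clones share the comparison clones in the rule, so unchanged clones were simulated against the same 21 others in 20 draws, and the others were split in 20 ways. The simulated clones stood at the mean of the others, with the spread between libraries and none between clones.

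Gene lists were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry, which asks whether the genes of a list move in 1 direction. In all, 32 lists with 668 genes were fixed, and 699 of their 718 entries were found. None of the mitochondrially encoded genes was in the table, so that list was not tested. Lists with too few measured genes were not tested with camera, which left 28 lists in each comparison. The groups, tests, gene lists, a first set of alternatives and the rule for naming genes were fixed before the data were examined, and other alternatives, such as the weights and the scale of log2(value + 1), were added afterwards. That rule took, among genes past the threshold with a mean of at least 50 normalized counts in the higher group, the 12 with the largest difference in each direction, or the 20 with the largest smaller median difference under the rule of 11 of 21. From each list it took up to 4 members with the smallest p. Where no gene passed, it took the 5 with the smallest p in each direction and named them as not passing. Serpine2 and Slpi were named in every comparison. The published study of these clones is known to have picked both from these libraries, so they are not independent evidence. Some genes that the rule names are not reported here.

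Positions come from the GENCODE annotation of the same build, in which 23044 of 23479 symbols, 98.1%, had 1 position. The tests were checked on simulated data with 200 changed genes. For the intravasating comparison, run on 13637 genes, 40.3% of genes shifted by 1 on the log2 scale were called, 82.1% of those shifted by 2 and 86.4% of those shifted by 3, with 18 unchanged genes called. For lung metastases against tumors, run on 13702 genes, these shares were 37.3%, 85.1% and 90.9%, with 3 unchanged genes called. For clone E against clone T they were 74.6%, 100% and 98.5%, with 7 unchanged genes called. Any simulated spread between clones or specimens was drawn for each gene by itself, whereas lists of genes moved together across the real clones. The shares called may therefore not hold for the real comparisons, and a gene that did not pass may still have shifted. Under the rule of 11 of 21, 933 unchanged genes were called when the simulated clones were spread as the real ones are, and 0 when they had no spread. Alternatives covered the scale, the filter on low values, the scaling between libraries, the use of libraries as samples, a replicate block, each library, clone or specimen left out, weights from the recovered reads, and other tests of the lists.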

Results

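RNA was profiled in 23 clones of the 4T1 mouse mammary carcinoma line and in 4 specimens from mice, to find genes tied to intravasation, the entry of tumor cells into blood vessels. The clones had been followed in a pool. Clones E and T were the intravasating ones and 21 were non-intravasating, with 2 libraries per clone. The specimens were 2 orthotopic tumors, Tumor_1 and Tumor_2, and 2 lung metastases, Lung_1 and Lung_2, again with 2 libraries each. Recovered reads per library ran from 15581390 to 31609870 in the intravasating clones, from 8849257 to 27304778 in the other clones, from 12183058 to 17369960 in the tumors and from 16327693 to 20368740 in the lung metastases. The median number of genes with a read was 15154.5, 14905, 16499.5 and 18420 in these groups. Among lung metastases it was 20278 and 19868 in the libraries lettered A and 16604 and 16972 in those lettered B, which had more reads, so the A libraries stood apart for low genes. The ribosomal RNA precursor Rn45s took the largest share of reads in every library but B of Tumor_2, where Malat1, a nuclear long RNA, did so with 3.45%.

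Serpine2 and Slpi, which encode secreted inhibitors of serine proteases, stood at high levels in both intravasating clones. Serpine2, on chromosome 1 from 79794197 to 79861180 on the minus strand (mm10), encodes protease nexin-1, an inhibitor of thrombin and plasminogen activators. It had 5950.5 ± 639 normalized counts in clone E and 6997 ± 945 in clone T (SD, n = 2 libraries), against a median of 897 over the 21 others, whose values ran up to 9030 counts. It was higher in E than in 17 and higher in T than in 18 of the 21. Slpi, on chromosome 2 from 164354070 to 164389095 on the minus strand, encodes an inhibitor of neutrophil elastase. It had 6509 ± 69.5 counts in E and 4279 ± 1236 in T, against a median of 1037 and a range of 26.7 to 10949, and exceeded 15 and 14 of the others. Clones F and O had more Serpine2 than either intravasating clone, and clones D, G, O and W had more Slpi. The labels do not count these clones as intravasating.

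**Figure D1:**
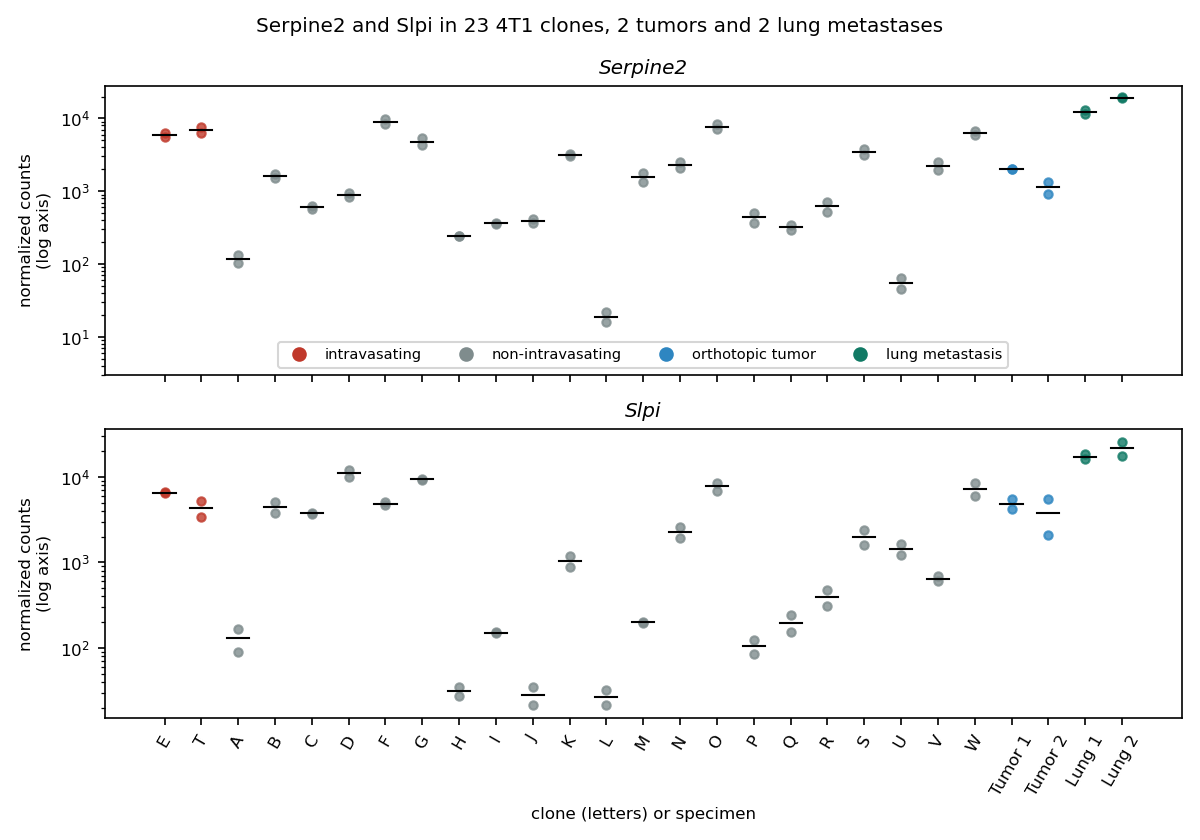
Normalized counts of Serpine2 and Slpi on log axes, with a point per library and a line at the mean of the 2 libraries, for 23 clones, 2 orthotopic tumors and 2 lung metastases. Clones E and T, in red, had 5950.5 and 6997 counts of Serpine2, clones F and O had more than both, and both lung metastases lay above every clone for both genes.

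Under the rule of higher in both clones than in at least 11 of the 21 others, 292 genes were higher and 219 were lower. Among those with the largest differences were 2 receptors for growth factors, Fgfr1 with 169 counts in E and 288 in T against a median of 12.1, and Ngfr, the low-affinity neurotrophin receptor, with 110.3 and 119 against 7.80. Aqp1, a water channel, had 980.3 and 409 counts against 104. Angpt1, a ligand of the endothelial receptor Tie2, had 632 and 157 counts against 32.3, and Pcolce, an enhancer of procollagen processing, had 3148 and 1860 against 758. The inflammatory caspases Casp1 (214 and 226 against 64.4) and Casp4 (106 and 119 against 23.0) were higher than in 13 of the others in each clone. Tgfbr3, a co-receptor of TGF-beta, had 839 and 597 counts against 247, and Mgp, an inhibitor of calcification, had 2465 and 991 against 451. Ucp1 was at 68.3 and 47.0 counts against 0.535, and Elovl4, an enzyme of very long chain fatty acid synthesis, at 185 and 136 against 33.5.

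Of 21 measured genes of cholesterol synthesis, 0 were higher and 15 were lower under this rule. Hmgcs1, which makes the precursor of mevalonate, had 1503 counts in E and 2186 in T against a median of 4555, Nsdhl had 480.3 and 736 against 1149, and Fdft1, or squalene synthase, had 859 and 1246 against 2090. Of 28 epithelial genes, 0 were higher and 14 were lower, among them the tight junction gene Ocln (233 and 178 against 423) and Elf3, an epithelial transcription factor (33.1 and 36.1 against 68.3). Neither list set E and T apart. The cholesterol list mean was 9.94 in E and 10.43 in T, and non-intravasating clones ran from 8.72 (S) to 11.86 (U). Clones F and S lay below both. For the epithelial mean, 8.23 in E and 8.40 in T, the non-intravasating clones B, O, S and W lay below both. The laminin genes Lama3 (23.1 and 211 counts against 290) and Lamb3 (36.7 and 462 against 606) were lower. They were among the 3 lower of 13 genes in the basal list and, like Agrn, among the 4 lower of 18 basement membrane genes, and 0 were higher in either list. Of 17 genes of MHC class I presentation, 3 were higher and 0 were lower, namely the immunoproteasome subunits Psmb8 (1585 and 961 against 540) and Psmb9 (796 and 437 against 259) and the transactivator Nlrc5 (650 and 540 against 323). In the list of genes tied to metastasis before, 3 of 26 were higher and 2 were lower. Spp1, or osteopontin, had 30158 and 15853 counts against 8374, and Gpnmb had 2699 and 825 against 552, whereas Ptgs2, the prostaglandin synthase COX-2, had 1503 and 4003 against 5542.

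Other lists moved both ways, in 1 direction only or not at all under the rule. Of 23 angiogenic ligands 4 were higher, Angpt1, Angptl2, Pdgfc and Thbs2, and 5 were lower, Pdgfb, Thbs1, Ptgs2, Cyr61 and Ctgf. Of 20 secreted protease inhibitors 3 were higher, namely Serpine2, Slpi and the cystatin Cst3 (4555 and 4380 counts against 3138), and 1 was lower. The study chose Serpine2 and Slpi on these samples, so this count is not independent evidence. Of 17 coagulation genes 2 were higher, Serpine2 and Pros1, the anticoagulant protein S (364 and 291 against 123), and 2 were lower, among them F2rl1. Wnt7a was at 27.7 and 81.6 counts against 826, 1 of 2 lower genes among 23 of the Wnt and Notch list, where 2 were higher. Higher and lower counts were 1 and 2 of 24 TGF-beta and BMP genes, 1 and 3 of 27 matrix proteases, 1 and 1 of 18 fibrillar collagens, 1 and 1 of 18 integrins, 2 and 2 of 25 chemokines, and 1 and 1 of 24 immediate early genes. Of the interferon response genes 2 of 30 were higher, Ifi44 (65.6 and 43.2 against 15.9) and Cxcl10, and 1 of 30 hypoxia genes, 1 of 19 mesenchymal genes, 1 of 6 macrophage genes, 1 of 10 fibroblast genes and 1 of 8 muscle genes were higher, with 0 lower in each. Both counts were 0 for 30 proliferation, 25 unfolded protein, 9 endothelial, 8 neutrophil, 9 pan-leukocyte and 6 lung epithelium genes and for 3 lymphocyte, 3 erythroid and 3 adipocyte genes. These limma contrasts rest on the spread between 2 libraries of a clone, and 292 and 219 genes were within what other pairs of clones gave: the median over 253 pairs was 340 higher and 347 lower, and 146 pairs had as many higher and 186 as many lower. Simulated unchanged clones against the same others gave a mean of 41.6 higher and 28.5 lower. These were drawn at the mean of the others with the spread between libraries only, so they show no excess of the 292 and 219 genes. In the check on simulated data with clones spread as the real ones are, 933 unchanged genes were called, higher and lower together. Independent lists would share 138.4 of the 1362 genes higher in E and 1386 higher in T, and 70.5 of the 838 and 1148 lower. With the others split, the median count was 323 higher and 231.5 lower. A required log2 difference of at least 1 left 23 genes higher and 19 lower.

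**Figure D2:**
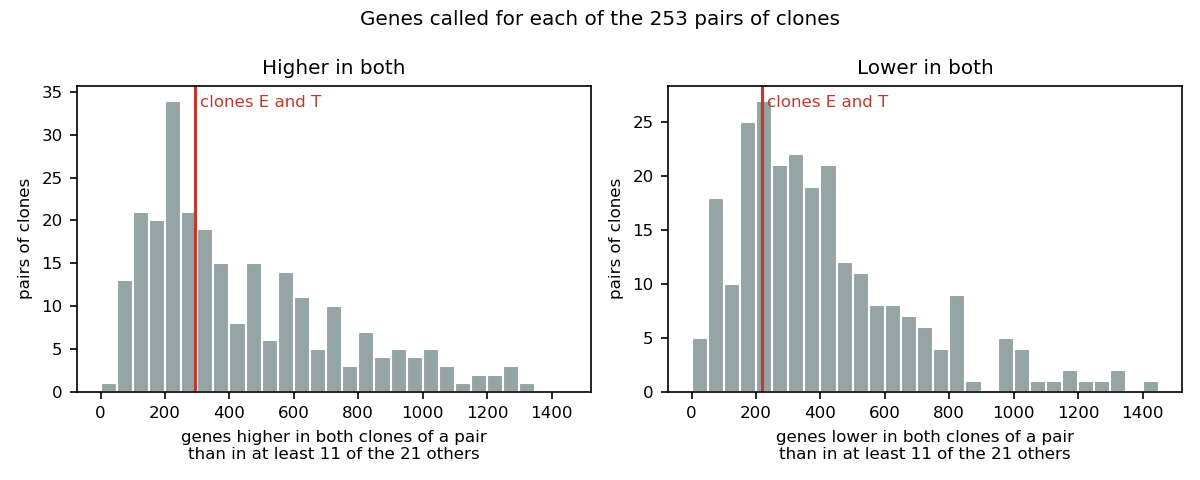
Number of genes higher (left) or lower (right) in both clones of a pair than in at least 11 of the 21 others, as histograms over the 253 pairs of clones, with the number of pairs on the vertical axis. The red lines mark clones E and T, at 292 and 219 genes, below the medians of 340 and 347.

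With the clone as the replicate, 0 of 13637 genes passed the limma test of intravasating (n = 2) against non-intravasating clones (n = 21). Serpine2 was 2.64 ± 1.35 higher and Slpi 2.50 ± 1.65 higher on the log2 scale (SE), each with an adjusted p of 1.00. The genes with the smallest p did not pass either. Zeb1, a transcription factor that represses epithelial genes, differed by 0.79 ± 0.21, with 21.9 counts in E and 60.1 in T against a median of 8.44, and Sobp differed by 1.08 ± 0.28 with 41.5 and 94.1 against 9.58. Armcx3 was at 52.9 counts in E and 0 in T, and Fam83a at 3.79 in E and 272 in T, so each rested on 1 clone, as did Slc35f3 (4.11 and 113 against 2.86). Without clone T the difference of Fam83a was -0.09. On the lower side were Ahnak at -0.82 ± 0.29, a large scaffold protein with 57558 and 41150 counts against 81097, the chloride channel Ano1 at -0.95 ± 0.34, the actin-binding Ablim1 at -1.23 ± 0.44, Zfp786 at -0.39 ± 0.14, and Chn1 at -0.96 ± 0.32, which was 0.23 higher without clone T. An unadjusted p under 0.05 was found for 109 genes, against 682 by chance, and limma with weights from the recovered reads passed 1 gene. Without clone E 4 genes passed and without clone T 1 gene passed, each resting on a single intravasating clone. Adjusted over the list alone, 1 of 19 mesenchymal genes, Zeb1, passed and over all genes 0 did.

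As lists, 4 kinds of gene were shifted in this comparison. Cholesterol synthesis was lower, with a median of -0.56 over 21 genes (camera adjusted p = 2.66e-07), and epithelial genes were lower, with a median of -0.55 over 28 genes (adjusted p = 6.61e-06). MHC class I presentation was higher, with a median of 0.28 over 17 genes (adjusted p = 0.00384), as was proliferation, with 0.07 over 30 genes (adjusted p = 0.0294). The estimated correlations between genes of these lists were far above the preset one, at 0.75, 0.579, 0.641 and 0.18 in this order. Each of the 4 calls had an adjusted p = 0.855 with an estimated correlation, and fry called 0 of 28 lists (smallest adjusted p = 0.996). Median, mean and test did not share a sign for the TGF-beta and BMP, coagulation, interferon, pan-leukocyte and protease inhibitor lists, which were not called.

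Ranked without a model, 2 genes lay above and 3 below all 21 others in both intravasating clones. Cln8, a protein of the endoplasmic reticulum, had 234 counts in E and 223 in T against at most 213, and Dhdds, which makes dolichol, had 555 and 579 against at most 506. Mettl22 had 35.9 and 35.4 counts against at least 38.5, Wfikkn1 had 14.6 and 14.7 against at least 15.8, and Prss27 had 2.98 and 2.11 against at least 3.14. These genes were named after their values were seen. Chance gives 53.9 genes per direction among 13637, and the median over all pairs of clones was 32 above and 34 below. With no filter on low values the count of 5 became 15, and with clone E or clone T left out, so that a single clone had to lie outside the others, it became 733 or 101. Without clone A, C, F, H or S it was 8, without B 9, and without N or W 10. The chance value of 53.9 holds for a pair of clones. A single clone lies outside the others by chance in many more genes, so 733 and 101 show no excess over it.

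Clones E and T differed from each other in 3919 of 13637 genes (28.7%), with 2090 higher in E and 1829 higher in T. Hexa, a lysosomal subunit of beta-hexosaminidase on chromosome 9 from 59539540 to 59565109, had 1.57 counts in E and 433 in T (log2 difference -3.60 ± 0.14 SE, limma adjusted p = 4.97e-19). Lcp1, the actin bundler L-plastin, had 552 and 5522 ± 318 counts (SD, n = 2 libraries), a log2 difference of -3.22 ± 0.15, and Has2, which makes hyaluronan, had 685 ± 40.9 and 4271 ± 89.9. The peptide hormone gene Cck had 26.4 counts in E and 555 in T, the adhesion molecule Icam1 32.7 and 355, and Fgfbp1, a carrier of fibroblast growth factors, 22.1 and 446. Higher in E were the urea transporter Slc14a1 (618 ± 313 against 3.80 ± 2.38), Peli2 (304 ± 61.7 against 3.80 ± 2.38), the receptor phosphatase Ptpru (719 against 32.0), the pentraxin Nptx1 (7193 against 1112), the iron-siderophore carrier Lcn2 (475 against 44.5), Chn1 (647 against 79.5) and Txnip, an inhibitor of thioredoxin (1722 against 361). Serpine2 did not differ past the threshold (-0.23 ± 0.16, limma adjusted p = 0.306), and Slpi was higher in E (0.63 ± 0.23, limma adjusted p = 0.0366).

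Cholesterol synthesis genes were higher in T, 17 of 21 over all genes and 18 adjusted over the list alone, and 1 was higher in E. Sc4mol differed by -1.14 ± 0.14 and Sc5d by -0.85 ± 0.15. Genes of MHC class I presentation were higher in E, 12 of 17 and 13 adjusted over the list alone, with 0 higher in T. Examples were Psme1 at 0.58 ± 0.13, the transporter Tap2 at 0.65 ± 0.16 and the class I heavy chain H2-K1 at 0.55 ± 0.13. The camera adjusted p was 1.98e-07 for cholesterol synthesis and 0.000538 for MHC class I, with an adjusted p = 0.294 and an adjusted p = 0.371 with an estimated correlation. Camera called none of the other lists, whereas fry called 13 of 28, among them basal genes (adjusted p = 4.98e-08), basement membrane (adjusted p = 1.18e-05) and TGF-beta and BMP (adjusted p = 0.000284). Of 28 epithelial genes 8 were higher in E and 9 in T (9 and 11 adjusted over the list alone), including the adherens junction gene Cdh1 at -1.19 ± 0.15 and the claudin Cldn3 at -1.57 ± 0.24. Of 24 TGF-beta and BMP genes 10 were higher in E and 3 in T (10 and 3 over the list alone), with Bmp7 at 1.24 ± 0.16 and its target Id3 at 1.03 ± 0.15. Of 13 basal genes 4 and 6 (4 and 6), of 26 metastasis genes 10 and 4 (10 and 6), of 23 angiogenic ligands 4 and 4 (4 and 5), of 27 matrix proteases 6 and 6 (6 and 6) and of 30 interferon response genes 8 and 2 (8 and 2) were higher in E and in T. Among these were Krt14 at -1.99 ± 0.18, Gpnmb at 1.60 ± 0.14, Tnc at -1.63 ± 0.12, Vegfa at 1.05 ± 0.15, Mmp11 at 1.97 ± 0.14 and Adam12 at -2.14 ± 0.13. Markers of macrophages (1 higher in E and 2 in T of 6), fibroblasts (2 and 1 of 10), endothelium (1 and 3 of 9) and leukocytes (3 and 2 of 9) also went both ways. Median, mean and test did not share a sign for the Wnt and Notch, angiogenic, immediate early, matrix protease, neutrophil, pan-leukocyte and unfolded protein lists, which were not called. Clone E differed from the non-intravasating clone B in 541 genes, the fewest of any pair. Its counts against the non-intravasating clones F (2156), N (2272) and W (2280), among others, were also below that against T. Against others, such as L (6549), they were above it. The number of genes between E and T was below the median of 5461 over all pairs of clones, whose counts ran from 541 to 8420, and 37 of 253 pairs had fewer. Without library A of clone T it was 2535.

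Among all 23 clones, 12971 of 13637 genes (95.1%) differed by the limma F-test. The median SD between clones was 0.27 on the log2 scale and that between libraries of a clone 0.14. Among the 12 genes with the widest ranges, 8 were highest in clone G. Lcn2, on chromosome 2 from 32384633 to 32388252, ran from 0 counts in clone P to 39411 in clone G. The cytokine Il1a ran from 11.7 counts in clone S to 24418 in G, the neutrophil chemokine Cxcl5 from 91.9 in V to 34278 in G, the complement component C3 from 11.2 in V to 11894 in G, the acute-phase gene Saa3 from 0 in D to 5744 in G, the chemokine Cxcl1 from 46.5 in W to 16206 in G, the monocyte chemokine Ccl2 from 2.04 in M to 5564 in G, and the interferon-induced Ifi44 from 3.31 in U to 6292 in G. Gpnmb ran from 22.2 in L to 11860 in W, and Fermt1, which links integrins to actin, from 9.05 in O to 6461 in J. Slpi and Serpine2 were again among them, with log2 ranges of 7.13 and 7.04. A range of at least 2 was seen for 1865 genes and of at least 5 for 129. By list the median range was widest for interferon response (5.10 over 30 genes, all of which differed), epithelial genes (3.93 over 28, all), cholesterol synthesis (3.43 over 21, all), pan-leukocyte markers (3.2 over 9, 8 of which differed) and chemokines (3.12 over 25, all), and it was 1.01 for proliferation (29 of 30 differed). Because clones had 2 libraries each, the F-test says that clones differed by more than their libraries did. Clone G stood apart from the other clones on the second principal component, which held 12.1% of the variance, and had an interferon list mean of 11.01 against 6.76 to 8.35 in the other 22.

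**Figure D3:**
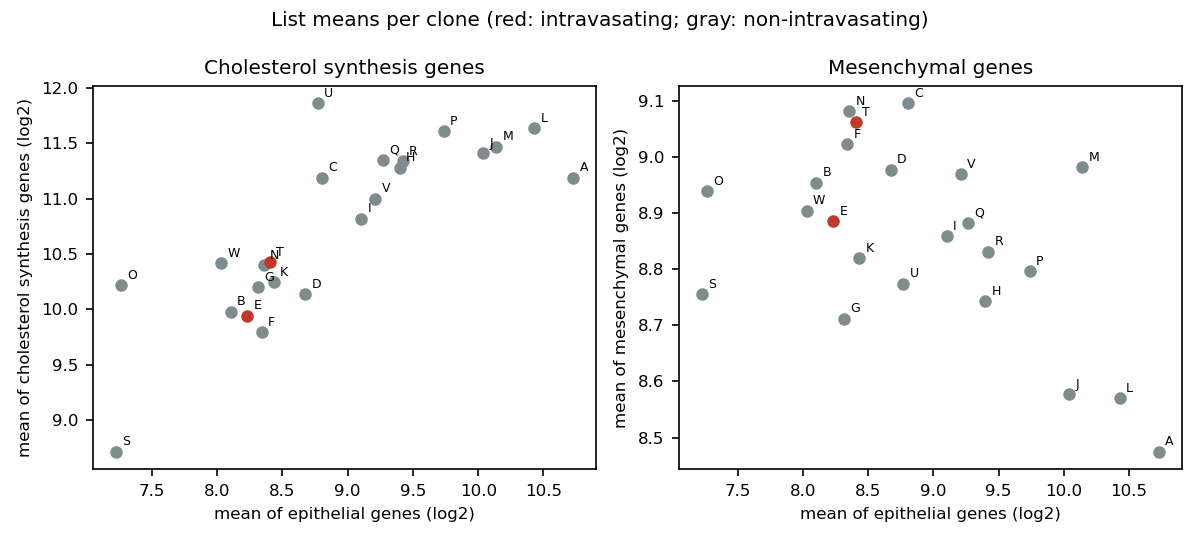
Mean log2 value of the cholesterol synthesis genes (left) and of the mesenchymal genes (right) on the vertical axes against that of the epithelial genes on the horizontal axes, with a point per clone and the intravasating clones in red. Clone E had an epithelial mean of 8.23 and clone T of 8.40, which rank 19 and 15 of 23 from the highest.

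In lung metastases (n = 2) against orthotopic tumors (n = 2), 26 of 30 interferon response genes rose, and 24 of 28 epithelial genes, 19 of 22 cholesterol synthesis genes and 14 of 25 chemokines and myeloid growth factors fell, while 5 of the last list rose. Camera called each of these 4 lists, with an adjusted p = 0.853 for each with an estimated correlation. Ifi44, on chromosome 3 from 151730922 to 151749960, rose by 3.88 ± 0.54 on the log2 scale (SE, limma adjusted p = 0.00143), with 5238 ± 4857 counts in lung metastases and 212 ± 7.65 in tumors (SD). Il1a, on chromosome 2 from 129299610 to 129309972, had 50.2 ± 24.2 counts against 3033 ± 441 (-4.90 ± 0.18, adjusted p = 4.19e-06). Cxcl5 had 395 ± 89.6 against 13776 ± 3459 counts, and Cxcl1 255 ± 11.1 against 4539 ± 584. Serpine2 rose by 3.30 ± 0.28, from 1582 ± 645 to 15791 ± 4929 counts (limma adjusted p = 0.000146), and Slpi by 2.21 ± 0.19, from 4334 ± 733 to 19322 ± 2947 (limma adjusted p = 0.000137). In all 4305 of 13702 genes (31.4%) passed, 2280 higher and 2025 lower in lung metastases, of which 378 were higher and 251 lower by at least 1.

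Other genes that rose by large amounts were Phex, an endopeptidase of phosphate balance (1832 ± 315 against 183 ± 21.3 counts), Cck (453 ± 113 against 24.0 ± 11.1) and Prune2 (508 ± 56.0 against 37.5 ± 14.7). Among genes that fell were Fgfbp1 (41.2 ± 12.7 against 1356 ± 10.3), the matrix protease Adamts1 (280.4 ± 22.3 against 3047 ± 154), Wnt7a (9.06 ± 5.22 against 424 ± 38.4), Rgs16 (44.3 ± 0.813 against 777 ± 82.3) and Adam12 (82.0 ± 27.7 against 1008 ± 150.1).

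Of 30 interferon response genes 26 rose, 28 adjusted over the list alone, and 0 fell. Oas2, which makes the activator of RNase L, rose by 3.37 ± 0.53, Irf9, a subunit of the interferon-activated transcription factor, by 1.74 ± 0.16, Rtp4 by 2.45 ± 0.27 and Dhx58, a regulator of RNA sensing, by 2.36 ± 0.29. The list's median was 2.10 (camera adjusted p = 2.38e-12, and adjusted p = 0.853 with an estimated correlation). The rise was uneven between specimens, since Lung_2 had 1666 counts of Oas2 and Lung_1 had 327, and the list mean was 10.74 in Lung_2, 9.38 in Lung_1, 8.06 in Tumor_1 and 8.08 in Tumor_2. The macrophage list moved in the same order in the lung specimens, at 7.42 in Lung_2 and 6.74 in Lung_1 against 6.54 and 6.44 in the tumors, as did fibroblast genes, at 7.79 and 6.84 against 6.89 and 6.85. Of 18 MHC class I genes 5 rose and 0 fell (5 and 0 adjusted over the list alone), among them H2-T23 at 1.48, Psmb9 at 1.05 and Psmb8 at 0.82 (camera adjusted p = 0.00735, and adjusted p = 0.853 with an estimated correlation).

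Of 28 epithelial genes 24 fell, 24 adjusted over the list alone, and 0 rose, or 2 over the list alone and 2 with quantile normalization or a common total. Esrp1, a splicing regulator of epithelial cells on chromosome 4 from 11331933 to 11386783, had 41.5 ± 24.9 counts against 1076 ± 199.5, the keratin Krt7 661 ± 122 against 3649 ± 195 and Ocln 35.6 ± 4.17 against 319 ± 7.93. Krt8 and Krt18, keratins of simple epithelia, were not past the threshold, at 6652 against 4852 and 9203 against 7597 counts. The camera adjusted p was 5.71e-13, and the adjusted p = 0.853 with an estimated correlation. Of 12 basal genes 7 fell and 2 rose (7 and 3 adjusted over the list alone), with Krt14 at -1.91, Lamb3 at -1.65 and Lama3 at -1.25, and Itgb4 at 1.02 (camera adjusted p = 0.0411, and adjusted p = 0.853 with an estimated correlation). Of 21 mesenchymal genes 3 rose and 0 fell (1 and 0 adjusted over the list alone), the matrix protein Tgfbi at 1.76 ± 0.27 and the transcription factors Zeb2 at 0.44 ± 0.13 and Twist1 at 0.36 ± 0.12, and the list was not called (camera adjusted p = 0.154).

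Of 22 cholesterol synthesis genes 19 fell and 0 rose (19 and 0 adjusted over the list alone). On the log2 scale Fdps was at -1.35 ± 0.13 and Sc5d at -1.33 ± 0.11, and the camera adjusted p was 8.01e-12, with an adjusted p = 0.853 with an estimated correlation. Of 25 chemokines and myeloid growth factors 14 fell and 5 rose (15 and 6 over the list alone). Cxcl3 had 20.9 ± 3.67 counts against 511 ± 52.6, Cxcl16 was at -2.65 ± 0.10, and Cxcl10 was among those that rose, at 1.03 ± 0.27 (camera adjusted p = 0.000356, and adjusted p = 0.853 with an estimated correlation). Of 23 angiogenic ligands 9 fell and 4 rose (9 and 4 over the list alone). Ctgf, at -2.62, and Cyr61, at -2.54, are targets of the Hippo pathway, Pdgfb was at -2.27 and Thbs1 at -1.81, whereas Angpt1 rose by 1.89 and Angptl2 by 1.74. Of 25 genes of unfolded protein and amino acid stress 9 fell and 2 rose (9 and 2 over the list alone), with the serine synthesis genes Psat1 at -0.88 and Phgdh at -0.77 and the mitochondrial Shmt2 at -0.91. Of 30 hypoxia genes 11 rose and 1 fell (12 and 1 over the list alone), with Bnip3 at 1.17, Pdk1 at 1.10 and the carbonic anhydrase Car9 at 1.04, and Adm at -1.57. The camera adjusted p was 0.00554 for angiogenic ligands, 0.00554 for the stress genes and 0.0402 for hypoxia, each with an adjusted p = 0.853 with an estimated correlation. With the A libraries alone the hypoxia median was -0.02.

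Of 19 macrophage genes 7 rose, 1 fell and 11 did not pass in lung metastases (11 rose and 1 fell over the list alone, camera adjusted p = 0.00554, and adjusted p = 0.853 with an estimated correlation), and of the 6 that the clones also express 1 rose and 1 fell. The lysozyme gene Lyz2 had 1341 ± 693 counts against 427 ± 128 and C1qc, of the complement C1q complex, 107 ± 74.8 against 10.4 ± 0.998, while Cd14 fell by 0.39. Of 13 pan-leukocyte genes 6 rose, 0 fell and 7 did not pass (7 rose and 0 fell over the list alone, camera adjusted p = 0.00778, and adjusted p = 0.853 with an estimated correlation), with Itgb2 at 0.73 and Arhgdib at 0.53, and of the 7 that the clones also express 3 rose. Lists not called were fibroblast (2 rose and 1 fell of 11), endothelial (3 and 1 of 12), neutrophil (3 and 1 of 7), lung epithelium (1 and 1 of 6) and muscle (0 and 1 of 7), and over each list alone these were 2 and 1, 3 and 1, 3 and 1, 1 and 1, and 0 and 0. In the secreted protease inhibitors 8 of 19 rose and 1 fell (9 and 2 over the list alone). Rises and falls were 6 and 6 of 19 in coagulation (6 and 7), 8 and 4 of 24 in TGF-beta and BMP (10 and 5), 8 and 4 of 25 in Wnt and Notch (10 and 7), 7 and 7 of 27 in the metastasis list (7 and 7), 5 and 8 of 28 in matrix proteases (6 and 8), 5 and 3 of 23 in fibrillar collagens (5 and 3), 4 and 5 of 18 in basement membrane (5 and 5), 5 and 4 of 20 in integrins (8 and 5), 3 and 2 of 30 in proliferation (1 and 0) and 4 and 6 of 24 in immediate early genes (4 and 7), with the counts over each list alone in parentheses. The Wnt and Notch median was 0.09 and its mean -0.03, the basement membrane median was 0.10 and its mean -0.14, the median of the metastasis list was 0.10 and its mean -0.10, and the matrix protease median was 0.03 and its mean -0.23. With 2 specimens per group and 4 in all, the count of 4305 became 1317 without Tumor_1, 1561 without Tumor_2, 2848 with the A libraries alone and 325 with the B libraries alone. With the B libraries alone 14 interferon response genes still rose, 9 epithelial genes fell and 0 cholesterol synthesis genes passed, and 0 macrophage genes rose without Tumor_1 or without Tumor_2. Interferon response genes that rose numbered 11 and 12 without those tumors, and epithelial genes that fell 15 and 19.

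**Figure D4:**
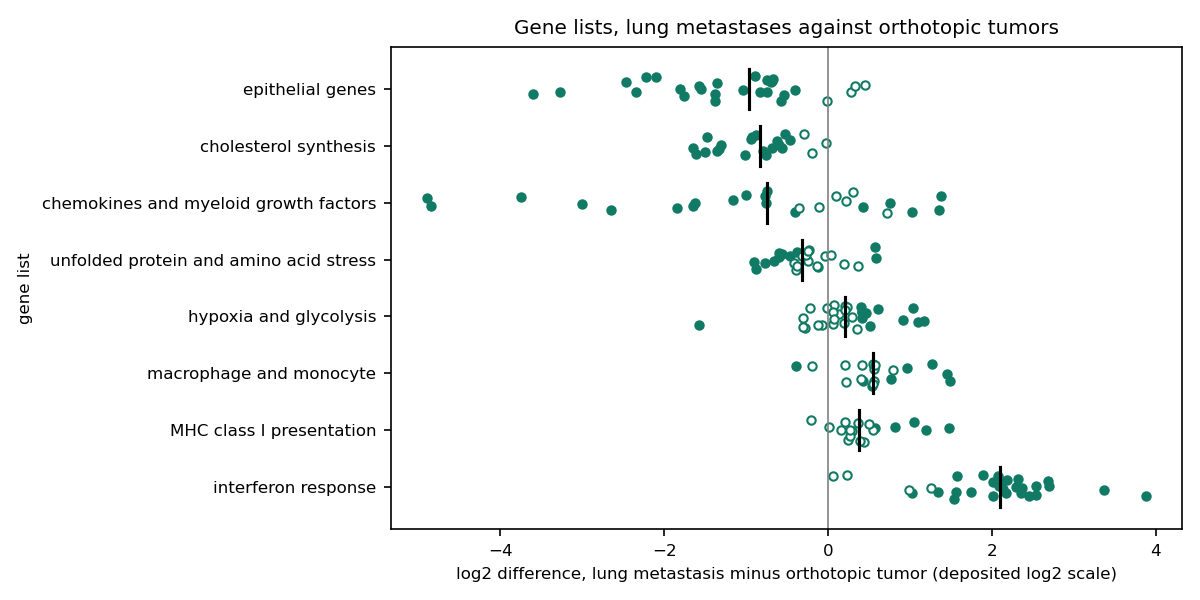
Log2 difference of lung metastases minus orthotopic tumors for each gene of 8 lists, with a point per gene, filled where the gene passed the limma test, and a vertical bar at the list's median. Interferon response genes lay around a median of 2.10 and epithelial genes around a median of -0.96.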

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

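The tests of whether other pairs of clones give as many genes, for the intravasating comparison and for the rule of 11 of 21, were chosen after the counts were seen.

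In clones E and T 243 genes moved in opposite directions, higher in one clone and lower in the other than in at least 11 of the 21 others, which drew attention because both clones carry the same label. Of these, 148 were higher in E and lower in T, among them Peli2, Nptx1 and Mgat3, and 95 went the other way, among them Hexa, Lcp1 and Has2. All 243 passed the test between E and T, as did 3919 of 13637 genes, but this adds little here, since the selection by itself sets both clones on opposite sides of other clones. Independent lists would give 199.8 such genes, a value that leaves out the comparison clones shared by both lists.

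Medag, a gene tied to fat cell development, had 8.117 normalized counts in library B of Tumor_1, while the other tumor libraries lay between 5.693 and 5.843, a gap of 0.938 of the whole range. Among 58 groups of libraries tested in this way 1 such value was found, and chance gives 2.9. All of these values are low next to the 340 counts of Medag in the lung metastases.

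The pattern weighed here is the set of 292 genes higher in both intravasating clones than in at least 11 of the 21 others. Chance cannot be excluded for it, since 146 of all 253 pairs of clones gave as many genes, with a highest other count of 1310, nor for the 5 genes outside all others, since 249 of 253 pairs gave as many, with a highest other count of 611. For the 0 genes of the limma test such a count says nothing about chance, since any pair reaches 0, as all 100 drawn pairs did, with a highest other count of 149 and 27 pairs with a gene past the threshold. Pairs that called several times as many genes point to a structure among the clones. The 292 genes crowded on some chromosomes, with a chi-square of 71.8 that was reached in 0.05% of 2000 random draws, the smallest share the draws can give, and with 34 genes on chromosome 9 where 16.7 were expected, 35 on chromosome 4 (18.0 expected) and 23 on chromosome 15 (11.9), so extra copies of chromosome segments may account for some of them. The 219 lower genes crowded too, with a chi-square of 66.5 and with 24 genes on chromosome 19 (7.61 expected) and 18 on chromosome 13 (8.63). For their own sets of higher genes, 217 of 253 pairs of clones had as large a chi-square. That value grows with the size of a set, and the sets ran from 28 to 1310 genes, so the 217 does not compare crowding alone. Such copies may mark other clones too, and a role of single genes such as Serpine2 in intravasation was not tested by these libraries.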

How the results depend on the processing

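The scale of log2(recovered normalized count + 1), the weights, the omission of library B of Tumor_2 or of clone G, and the restriction to genes of the clones were chosen after seeing the data, and the other alternatives were planned. The count-model tools planned for recovered reads were not run, since the deposited unit is log2. Counts below stayed within 1.5 times the reported one except as given, and the cause was not tested unless fewer genes or samples show it. Higher genes outnumbered lower ones between lung metastases and tumors (2280 and 2025), but not with quantile normalization (2195 and 2297) or without Lung_2 (1913 and 1942), Tumor_1 (644 and 673) or Tumor_2 (711 and 850), and under the rule of 11 of 21 (292 and 219), but not with a pseudocount of 0.1 (202 and 207). Between E and T (2090 and 1829) a common total gave 2479 and 1536. The 5 genes outside all other clones became 15 with no filter, 3 with at least 50 counts, 8 with a common total, and 5 to 733 with a clone left out (733 without E and 101 without T, where a single clone is compared). The 0 genes of the intravasating comparison became 0 to 4 with a clone or letter left out (4 without E, 1 without T) and 1 with weights. Under the rule of 11 of 21, 23 higher and 19 lower genes had a log2 difference of at least 1 in each contrast, and 0 and 0 held against all 21 others. With another clone left out the counts were 313 to 402 higher and 229 to 317 lower. Fewer than 11 others sufficed here, since the bar followed the number of others left. These larger counts therefore mix the lower bar with the loss of a clone. Clone E against T gave 2535 to 3042 genes with a library left out, the lone library being assumed to vary like the others, and 2947 with its 4 libraries alone. Lung metastases against tumors gave 2645 genes with no filter, 2848 with A and 325 with B libraries alone, and 325 to 4650 with libraries or a specimen left out (1317 without Tumor_1, 1561 without Tumor_2), a lone specimen being assumed to vary like the other group. Without library B of Tumor_2 it was 4455, and among genes of the clones 4257. Of the gene list calls (4, 2 and 11), 0, 0 and 0 held with an estimated correlation, and fry called 0, 13 and 0. For lung metastases against tumors that correlation was estimated from 4 specimens. The smallest unadjusted camera p with it was 0.113, for epithelial genes. With so few specimens this check could hardly call any list, so it leaves the 11 calls unsettled.

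The replicate block changed no count by over 1.5 times. The letters gave no general sign of pairing, since the A minus B differences of 2 clones correlated at a median of 0.0802 (-0.502 to 0.637), although 44.7% of clone pairs lay over 0.1. The specimen numbers gave no sign of pairing either (correlation -0.0986), but 1 such value cannot tell whether equal numbers share a mouse. As a block they gave 4472 genes against 4305, and the library letter as a block gave 4207 genes between E and T against 3919. Libraries as samples with a correlation within specimen gave 5308, or 5015 with the letter as a block. That correlation was estimated at -0.258, or -0.341 with the letter, so libraries of a specimen were no more alike than others of the tissue. These larger counts therefore add no certainty. Among named genes 3 reversed. Without clone T the log2 difference of Fam83a, intravasating against other clones, was -0.0870 and that of Chn1, intravasating against other clones, 0.23, and without clone E they were 2.78 and -2.15. Tnni2, lung vs tumor specimens, was at 0.0265 with the A and -1.01 with the B libraries. Under at least 1 alternative 24 of 120 named genes between E and T (74 of 1667 values), 71 of 71 under the rule of 11 of 21 (165 of 2272 values, 71 of them against all 21 others) and 65 of 116 between lung metastases and tumors (1982 of 2184 values kept theirs) lost their call or reversed, 4 of 415 values in the intravasating comparison gained one, and 0 of 120 among all clones changed. Depth limits genes near the floor of 5.03, where a difference on the deposited scale is compressed.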

Other observations

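The tests of host RNA against the genes that fell in lung metastases were chosen after the result was seen, as were the counts of genes confined to single clones and the comparison of clones E and T, each by itself, with the lung metastases.

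Across the 23 clones the mean of the epithelial genes moved with several other lists. Of 19 relations computed with 100000 resamples, it correlated most with the means of the basal list without its shared members (r = 0.939, rho = 0.947), basement membrane (r = 0.898, rho = 0.866), Wnt and Notch (r = 0.832, rho = 0.827) and cholesterol synthesis (r = 0.801, rho = 0.825). The permutation p of each r and rho was 1e-05, the smallest possible, with an adjusted p = 6.33e-05, except for Wnt and Notch, where both were 2e-05 with an adjusted p = 9.5e-05. For cholesterol synthesis r was 0.824 without the 2 clones farthest from the median, and 0.801 and 0.798 in the libraries lettered A and B. For the other 3 lists r without those clones was 0.94, 0.851 and 0.802, and by letter it was 0.94 and 0.937, 0.889 and 0.889, and 0.807 and 0.849. MHC class I presentation went the other way (r = -0.564, permutation p = 0.0047, adjusted 0.016, and rho = -0.697, permutation p = 3e-04, adjusted 0.00114), with r = -0.62 without those 2 clones and -0.579 and -0.531 by letter. For the interferon response r was -0.304 (permutation p = 0.162, adjusted 0.236) and rho was -0.575 (permutation p = 0.00497, adjusted 0.0135), and r was -0.402 without those clones and -0.306 and -0.299 by letter. The values of the clones were not independent of their shared parent line.

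Some genes were on or off in single clones. In 15 genes 1 clone had at least 100 normalized counts and every other clone under 10, and 14 of these were in clone G, among them the chitinase-like Chi3l1 (631 counts), Oas2 (1808), the receptor Pilra (901), Il6 (139.8) and lactoferrin, Ltf (138). The remaining gene was the netrin receptor Unc5d in clone R, with 175 counts. In 6 genes 1 clone had under 10 counts and all others at least 100. Fam111a had 6.58 counts in clone C and at least 423 elsewhere, Fermt1 and Arhgef3 had 9.05 and 9.71 in clone O, and Parvb and Lrrk2, both on chromosome 15, had 0.983 and 1.58 in clone S and at least 156 and 146 elsewhere. These genes were named after their values were seen. In the lung metastases Oas2 had 327 and 1666 counts and Chi3l1 0.449 and 0.825.

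For the genes that fell in lung metastases against tumors, host RNA diluting that of the tumor cells is the technical explanation weighed, and the evidence against it is limited. The highest host marker, Lyz2, had 1341 counts in lung metastases, above the median of 754.6 of the genes that fell by at least 1 in tumors, but Lyz2 is among the most abundant transcripts of macrophages and so bounds no share by itself. Genes under 10 counts in every clone together held at most 0.204% of a lung metastasis library, where a fall by 1 through dilution would need about as much host as tumor RNA. They held 0.0759% to 0.204% of the lung metastasis libraries and 0.0549% to 0.127% of the tumor libraries, so these ranges overlapped. In clone libraries it was 0.0123% to 0.0408%. The low share in lung metastases speaks against much host RNA. It is a lower bound, however, since it leaves out host RNA from genes that the clones also express. Of the 378 genes that rose by at least 1, 15, or 3.97%, were under 10 counts in every clone, among them Lyz2, C1qb and Col6a3, so host cells may account for these genes. For the others the source cannot be told, since expression in 1 clone is enough to leave this set and host cells may express the same genes. Oas2, for example, had 1808 counts in clone G, at most 8.07 in any other clone, and 327 and 1666 in the lung metastases. Signals from host cells that change expression in tumor cells stay open and were not tested, nor can chance be judged, because 4 specimens make only 3 splits, with 4305 genes in the real one and at most 0 in the others.

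A candidate biological explanation for the differences between lung metastases and tumors is another mixture of the clones' expression states. Of the sum of squares of these differences, 62.8% lay in the space spanned by the 23 clones, 37.9% on its first component. For the difference between the lung metastases and between the tumors the share in this space was 24.4% and 19.9%. The space allows weights of any size and sign on the log2 scale. Its share therefore also takes in values that no mixture reaches, and it cannot decide whether there was a mixture. Clones E and T had a mean correlation of 0.483 with the difference across genes, which are not independent replicates, and 6 of 253 pairs were as high, with a highest other of 0.511, but clone E ranked 1 (0.551) and clone T 7 (0.415), below the non-intravasating D, B, S, N and W. Without the first component of the clones the mean was 0.278, with 7 pairs as high, and here T ranked 1 (0.458) and E 8 (0.0973), so the clone nearest to the difference was E with this component and T without it, and the 2 never ranked together above all others. A mixture of states stays a hypothesis, found and tested on the same 4 specimens. Both lung metastases lay above every clone for Serpine2 and Slpi, levels that no mixture of these 23 clones alone reaches. That limit covers these 2 genes only. Changes of state within cells could give differences like those seen, for these genes and for others.

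For the epithelial and mesenchymal lists, an axis shared by both was weighed. Their means correlated at -0.515 across the 23 clones (permutation p = 0.0118, adjusted permutation p = 0.0292, and -0.528 and -0.498 by letter), but rho was -0.357 (permutation p = 0.0944). Without clones A and L, the farthest out, r was -0.231 (permutation p = 0.315), so the relation rests on those clones. Clones O and S, with the lowest epithelial means of 7.26 and 7.22, had mesenchymal means of 8.94 and 8.76, inside the range of the others. No technical explanation was tested for this pattern.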
